A study of Caenorhabditis elegans with 6 samples.

How the data were processed

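Small RNA libraries came from isolated germ nuclei of worms of a strain with ISW-1 fused to eGFP and an auxin-inducible degron and with TIR1 expressed under the mex-5 promoter. Per the labels' protocols, worms were grown for 45 h at 22 °C and moved for 3 h to plates with 1 mM auxin or ethanol, and there were 3 libraries per condition. Per the labels' protocols, RNA was treated with the phosphatase CIP and then with the pyrophosphohydrolase RppH before library preparation, an order that favours RNA with a 5′ cap. The depletion of ISW-1 is at the level of protein and could not be checked in counts of piRNA windows.

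The deposited values were whole-number counts per piRNA precursor window, with no normalization. Per the file headers, they were made with featureCounts 2.0.3, with strand-specific counting, multi-mapping reads counted, each read reduced to its 5′ base and a read in more than 1 window counted for none, since the option that would assign it to several was not set. Per the file headers, the input was 1 merged alignment file per condition, so the 3 libraries of a condition had been pooled before counting. The labels' protocols name both a QIAseq miRNA kit and a Qiagen micro mRNA-Seq kit for library preparation, in the same words for all 6 libraries, and do not say which kit made which library. The aligner, the trimming, any filter on read length and any use of molecular identifiers were not given in the sources used here. PCR reads without molecular identifiers are not independent molecules, and counting intervals are then too narrow. Since multi-mapping reads were counted, precursors with identical sequence could share reads.

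Of the 15703 windows, 15702 were 24 bases long. The submitters' processing notes name the build ce11. The windows were nevertheless displaced from the positions of piRNAs of the same name in the Ensembl release 115 annotation of WBcel235, by −6 to 102 bases in all and by 1 to 38 bases on chromosome IV (median 33). No coordinates were converted. A window was called located when a piRNA of the same name lay on the same chromosome and strand within 200 bases, which held for 15318 windows, and 385 were not located. For located windows, the positions given are those of the annotated mature piRNA of 21 bases on WBcel235. Regions and gene context were taken from that position, or from the position in the deposited table where a window was not located.

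Because each condition had a single column, the tests chosen before the data were examined (edgeR's quasi-likelihood test across libraries, camera and fry for groups of windows, and permutation of libraries) could not be run, and no p-values were computed. They were replaced, after the layout of the table was known, by rules of size. Windows with at least 10 counts over both columns were tested, 1320 in all, which held 98.9% of ETOH counts and 99.0% of auxin counts. Their log2 ratios came from edgeR 4.0.16 (cpm with a prior count of 2, TMM scaling) in R 4.3.3, and a window was called lower or higher at a ratio of at least 2-fold. Raw ratios are ratios of the deposited counts with no scaling and no prior count. Scaled ratios of single named windows, with their intervals, are raw ratios divided by the TMM ratio, also with no prior count. Scaled log2 ratios used for calls and medians keep the prior count of 2. TMM removes a change common to most windows, so scaled ratios are relative to the typical precursor. Intervals of a ratio of counts were exact conditional binomial intervals, and intervals of a share were Clopper-Pearson intervals, at 95% and for counting error only. For a count of 0, a fold was given as a bound against a floor of 3 counts in the column. The number of windows that counting error alone would call was taken from redraws with the TMM ratio as the sole difference.

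The groups of windows were fixed before the data were examined: the small cluster of chromosome IV (4.5 to 7 Mb), its large cluster (from 13 Mb), the rest of chromosome IV, the other chromosomes, windows inside protein-coding genes and the most abundant 10% of tested windows. For each group, the median scaled log2 ratio minus that of the other tested windows was given with an interval from 1000 Poisson redraws of all counts. Except for the most abundant windows, its median was also placed among 10000 random lists of equal size matched on abundance decile. Groups with and without the upstream motif were not analysed here, since no genome sequence was used. Lists of other RNA classes were not used here, as the table held piRNA windows alone. For detection at an equal total of window counts, the ETOH column was thinned without replacement to the auxin total in 20 draws.

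The rule for named windows was adapted to pooled columns: the 10 lower and the 10 higher windows whose 95% interval lay farthest from no change at its nearer bound, the 10 most abundant by mean scaled CPM, and 21ur-1 and 21ux-1 by name. No window named 21ux-1 was analysed here. The original rule required an adjusted p and separated libraries. Host genes are protein-coding genes that contain the annotated piRNA, with exon or intron and strand from the same annotation.

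The procedure was tested on simulated counts with a common factor of 0.64 and 200 changed windows. These counts had Poisson counting error alone, with no spread between libraries or from PCR. The shares below therefore do not give the error rates in the deposited counts. The recovered factor was 0.642. Of 1226 simulated windows tested in the comparison of auxin with ETOH, the 2-fold rule took 92.7% of those set 4-fold lower, 37.2% of those set 2-fold lower, 34.8% of those set 2-fold higher, 100% of those set 4-fold higher and 5.74% of unchanged ones. Alternatives were library totals, DESeq2 1.42.0 size factors and no scaling, no filter and edgeR's filterByExpr, other prior counts and a minimum of 100 counts, and the removal of overlapping, unlocated or dominant windows. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.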

Results

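Small RNA was sequenced from germ nuclei of a Caenorhabditis elegans strain in which ISW-1 carries a degron tag, meant for its removal from the germ line by auxin. ISW-1 is an ATPase of the ISWI family of chromatin remodellers, and its depletion could not be checked in these counts. Worms were kept for 3 h on plates with 1 mM auxin (knockdown) or with ethanol alone (ETOH, the control), and each condition had 3 libraries. The RNA had been treated so that molecules with a 5′ cap were favoured, and the values were counts of reads whose 5′ base lay in a piRNA precursor window. piRNAs of the worm, also called 21U-RNAs, are germline small RNAs made from short capped precursors, most of them encoded in a pair of broad regions of chromosome IV. The counts held 1 pooled column per condition, so the difference between conditions had no replicate check. Intervals are 95% intervals that cover counting error only. The pooled ETOH column held 461069 counts and the pooled auxin column 351565, over 15703 windows.

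The comparison asked whether loss of ISW-1 changed the amount of piRNA precursor. The auxin column held 0.763 times the counts of the ETOH column (interval 0.759 to 0.766), a deficit of 109504 counts. A single window, 21ur-2844 on chromosome IV, held 64236 of these, or 58.7% of the deficit: it had 109547 counts in ETOH and 45311 in auxin, a ratio of 0.414 (0.409 to 0.418). This window could not be matched to an annotated piRNA, and its position in the table (IV:8428702-8428725, minus strand) fell within the small nucleolar RNA gene T26A8.6 (IV:8428614-8428739, minus strand, WBcel235), with both flanking piRNA windows displaced by 14 bases from their annotated positions. Without it the columns held 351522 and 306254 counts, a ratio of 0.871 (0.867 to 0.875). Because the table held piRNA windows alone, the depth of the whole libraries was unknown, and a change shared by all windows could not be separated from a difference in depth.

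Among the 10 most abundant windows, raw ratios ran from 0.414 in 21ur-2844 to 1.12 in 21ur-3972. The window of 21ur-4459 (IV:14723071-14723091, plus strand, outside protein-coding genes) had 84352 counts in ETOH and 84612 in auxin, a ratio of 1.00 (0.994 to 1.01). Counts were higher in auxin for 21ur-3972 (IV:17156627-17156647), at 18925 and 21126, and for 21ur-4930 (IV:16838285-16838305), at 16781 and 17461. The window of 21ur-5622, in an intron of the serpentine receptor gene srv-32 on the opposite strand (IV:6281641-6281661), had 9427 and 7963 counts, a ratio of 0.845 (0.820 to 0.870). The other abundant windows, 21ur-12226, 21ur-6064, 21ur-2937, 21ur-4429 and 21ur-12947, had raw ratios from 0.895 to 0.956, and that of 21ur-12226, placed on the mitochondrial genome, was not matched to an annotated piRNA. These 10 windows, 21ur-2844 included, held 63.6% of ETOH counts and 64.3% of auxin counts. Among the 132 most abundant tested windows, 108 had fewer raw counts in auxin, and their median raw log2 ratio was −0.31. Relative to the other tested windows, their median scaled log2 ratio was higher by 0.42 on the log2 scale (0.37 to 0.49), and by 0.27 when the most abundant 25% of windows were taken.

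Most of the less abundant precursors were lower in auxin in raw counts. Of 1320 windows with at least 10 counts over both columns, 1036 had fewer counts in auxin and 241 had more, and the median raw log2 ratio was −0.66 (quartiles −1.38 and −0.15). The median was −0.68 in the 398 windows with 10 to 20 counts, −0.85 in the 385 with 20 to 50 and −0.20 in the 71 with 1000 or more. In raw counts, 514 windows were at least 2-fold lower and 53 at least 2-fold higher in auxin. Among the 330 windows with at least 100 counts, 91 were at least 2-fold lower and 0 at least 2-fold higher in raw counts, and the interval of the raw ratio lay wholly below 1 in 217 and wholly above 1 in 13.

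**Figure D1:**
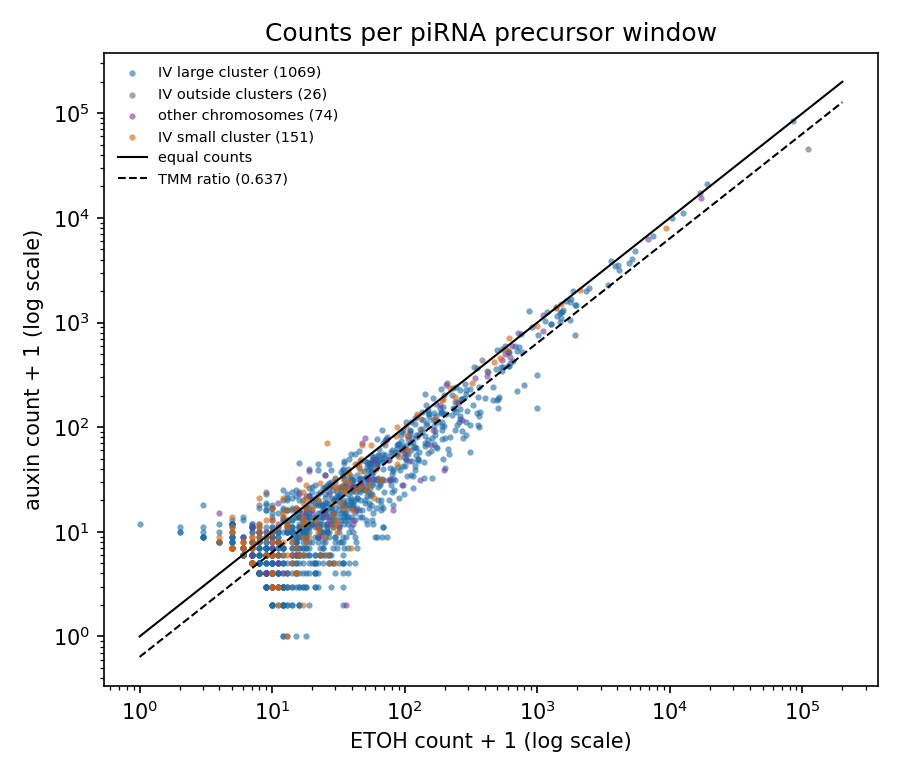
Counts of each tested window in the pooled auxin column (vertical, count + 1, log scale) against the pooled ETOH column (horizontal, count + 1, log scale), coloured by genomic region. The solid line marks equal counts and the dashed line the TMM ratio of 0.637; the most abundant windows sit near the solid line except 21ur-2844, with 109547 and 45311 counts.

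Relative changes were taken after TMM scaling, which set the auxin column at 0.637 of the ETOH column, a shift of −0.65 on the log2 scale. Relative to that shift, 196 windows were at least 2-fold lower and 111 at least 2-fold higher in auxin, so that 63.8% of these windows were lower. The share was 78.7% when only library totals were used (259 lower and 70 higher) and 92.4% without scaling (439 and 36, with the same prior count of 2). It was 51.2% when all windows with a count were scaled and compared (533 and 508). Counting error alone, with no change in any window beyond the shift, gave on average 42.2 lower and 27.8 higher windows, of which 60.3% were lower. Of the windows with at least 100 counts, 27 were at least 2-fold lower and 7 at least 2-fold higher after scaling. The spread between windows was therefore larger than the counting error of independent reads. PCR copies, if reads were counted without molecular identifiers, would widen that error by an unknown amount. The spread could not be set against the spread between libraries.

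The lower and the higher named windows were picked from 1320 by the intervals printed here, which make no allowance for that choice. Their ratios may therefore lie too far from no change. Of the 10 named windows lower in auxin, 2 had enough counts for a narrow interval. The window of 21ur-6225 (IV:14700678-14700698, plus strand, outside protein-coding genes) had 986 counts in ETOH and 152 in auxin, a scaled ratio of 0.242 (0.203 to 0.287). The window of 21ur-4221 (IV:16625142-16625162, minus strand, outside protein-coding genes) had 311 and 57 counts, a scaled ratio of 0.288 (0.213 to 0.382). The gene jac-1, which encodes a catenin of the p120 family, held 2 further windows in introns: 21ur-15689 on the opposite strand (IV:16004715-16004735) had 73 and 8 counts, and 21ur-2384 on the same strand (IV:16014195-16014215) had 66 and 8. The other 13 tested windows in jac-1 introns were counted after these values were seen. Their scaled log2 ratios, with a prior count of 2, ran from −2.01 to 0.59 (median −0.40). Of these 13, 4 were at least 2-fold lower, against 173 of 1069 tested windows in the large cluster and 196 of 1320 in all. Whether windows in jac-1 differed from their region was not tested. The annotated piRNA of 21ur-12617 lay over an exon of the histone methyltransferase gene set-25 on the opposite strand (III:13289701-13289721). The counted window lay at III:13289599-13289622, displaced by 102 bases, the largest displacement of a located window. This window had 35 and 1 counts, a scaled ratio of 0.0448 (0.00110 to 0.267). Its scaled log2 ratio with a prior count of 2 was −3.22. The window of 21ur-6478 (IV:15897704-15897724) had 17 counts in ETOH and 0 in auxin, at least 3.61-fold lower after scaling against a floor of 3 counts, with an interval of the scaled ratio that reached up to 0.380. The other windows of this set, 21ur-1073, 21ur-10357, 21ur-5934 and 21ur-5595, had 33 to 41 counts in ETOH and 1 to 4 in auxin, and the window of 21ur-5595 overlapped another window.

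Of the 10 named windows higher in auxin, that of 21ur-2305 (IV:16043696-16043716, minus strand, outside protein-coding genes) had the most counts, 865 in ETOH and 1288 in auxin. Its raw ratio was 1.49 (1.37 to 1.62) and its scaled ratio 2.34 (2.14 to 2.55). The window of 21ur-4908, in an intron of the metabotropic glutamate receptor gene mgl-3 on the same strand (IV:5442300-5442320), had 25 and 70 counts, a scaled ratio of 4.39 (2.75 to 7.24). The window of 21ur-2374, in an intron of Y40H7A.2 on the opposite strand (IV:15164703-15164723), had 15 and 44 counts, a scaled ratio of 4.60 (2.51 to 8.90). The window of 21ur-4423, in an intron of ssu-2 (IV:14361698-14361718), had 0 counts in ETOH and 11 in auxin, at least 5.75-fold higher after scaling against a floor of 3 counts, with an interval of the scaled ratio that reached down to 3.94. The other windows of this set, 21ur-5031, 21ur-11407, 21ur-11706, 21ur-11378, 21ur-15109 and 21ur-9185, had 1 to 8 counts in ETOH and 9 to 23 in auxin. Intervals were wide at such counts, and that of the scaled ratio of 21ur-11407 ran from 2.23 to 681. The filter of edgeR's filterByExpr did not keep 21ur-4423, 21ur-11407, 21ur-11378 or 21ur-15109.

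**Figure D2:**
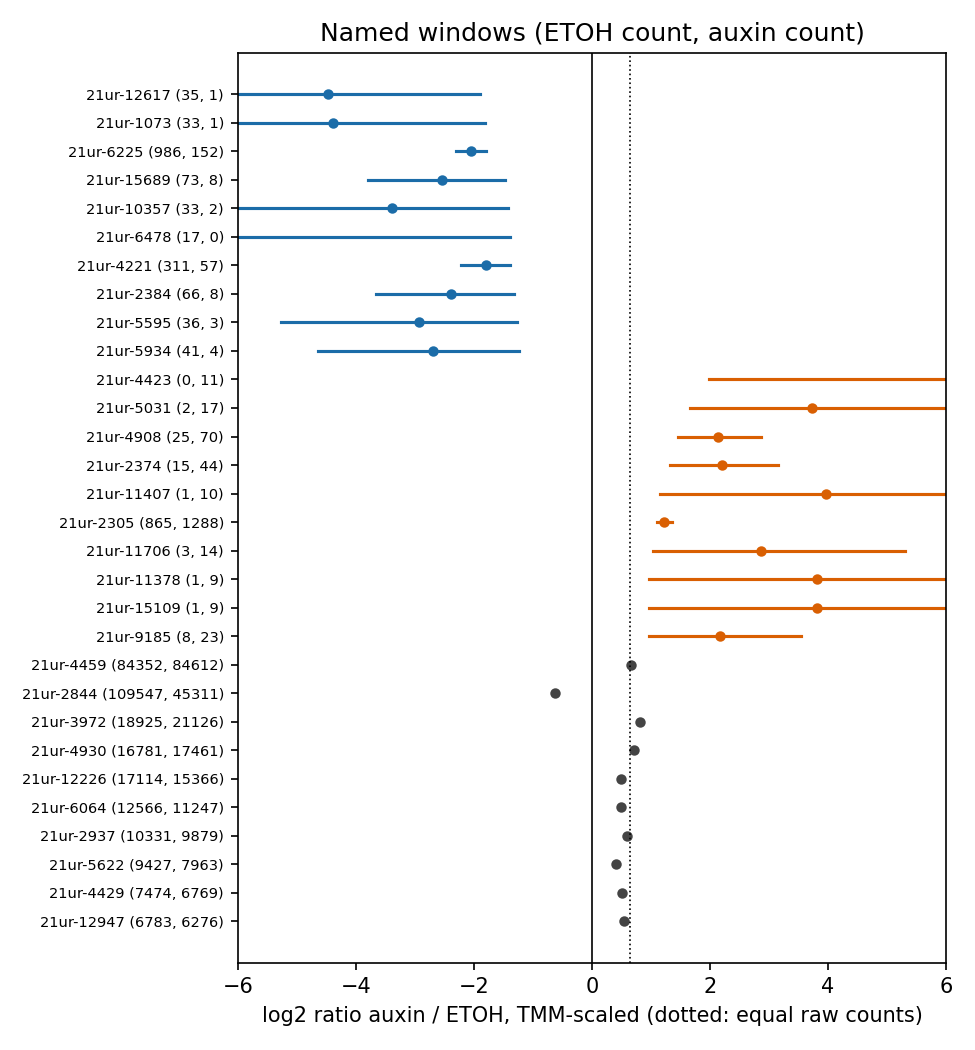
TMM-scaled log2 ratio of auxin to ETOH counts, with no prior count (horizontal), for the 10 lower, 10 higher and 10 most abundant windows, with 95% counting intervals as lines and the ETOH and auxin counts beside each name. The solid line marks the typical tested window and the dotted line equal raw counts; 9 of the abundant windows lie near the dotted line, while 21ur-2844, with 109547 and 45311 counts, lies far to its left; lines that reach the frame extend beyond it, and 2 windows with a count of 0 have no point.

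Ratios differed between the regions of chromosome IV. In the large cluster, from 13 Mb to the chromosome end, 867 of 1069 tested windows had fewer raw counts in auxin, and the median raw log2 ratio was −0.74. In the small cluster, from 4.5 to 7 Mb, 95 of 151 did, and the median was −0.25. After scaling, with a prior count of 2, the medians were −0.08 and 0.36, so the small cluster lay below equality in raw counts and above the typical window in scaled ones. After scaling, the small cluster was higher than the large one by 0.44 on the log2 scale (0.28 to 0.53), or 1.36-fold. Within windows of similar abundance the difference was 0.46 for those with 10 to 20 counts, 0.27 for 20 to 50, 0.40 for 50 to 100 and 0.47 for 100 or more. The median of the small cluster lay above all of 10000 random lists of equal size matched on abundance (95% of them between −0.18 and 0.10), and the median of the large cluster lay below all of its own (−0.03 to 0.02). These percentiles describe these pooled columns and are not tests between conditions.

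**Figure D3:**
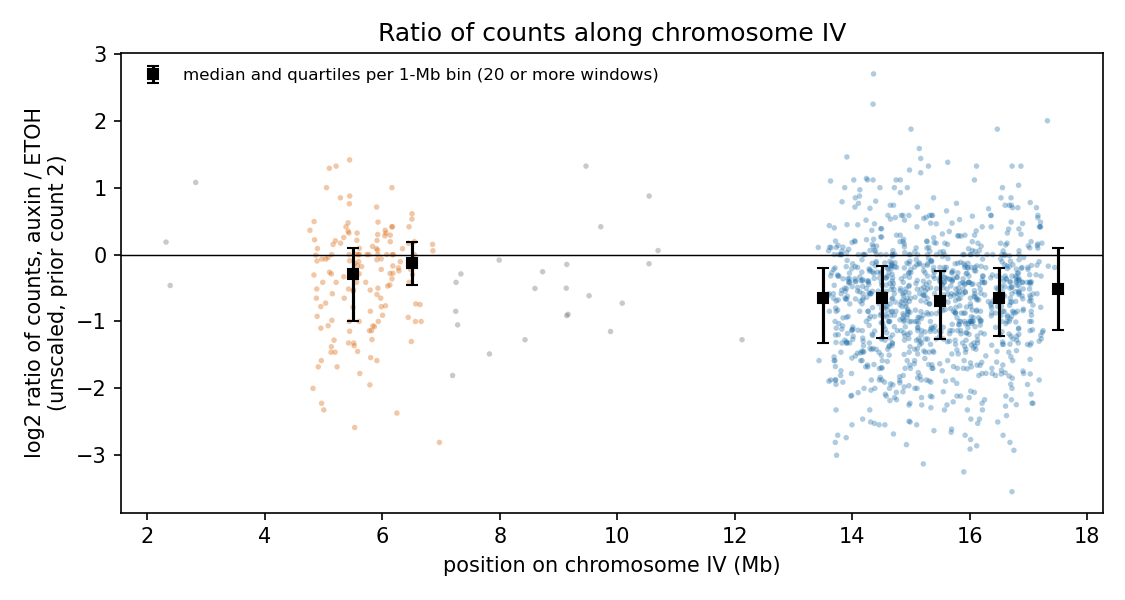
Unscaled log2 ratio of auxin to ETOH counts, with a prior count of 2 (vertical) of each tested window by position on chromosome IV in Mb (horizontal), in orange for the small cluster, blue for the large cluster and grey for the rest, with the median and quartiles of each 1-Mb bin that holds at least 20 windows in black. Medians were −0.29 and −0.13 from 5 to 7 Mb and between −0.69 and −0.51 from 13 to 18 Mb, and the 18 windows from 4 to 5 Mb, too few for a bin, had a median of −0.46.

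By share of all counts, the clusters moved little once 21ur-2844 was left out. The large cluster then held 83.3% of ETOH counts and 83.1% of auxin counts, and the small cluster 6.54% and 6.65%. The window of 21ur-4459 alone held 84352 of the 292652 ETOH counts and 84612 of the 254509 auxin counts of the large cluster. With 21ur-2844, the large cluster held 63.5% and 72.4%, the small cluster 4.99% and 5.79%, and the rest of chromosome IV 24.3% and 13.5%.

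Most windows elsewhere in the genome were also lower in raw counts. On chromosome IV outside the clusters, 20 of 26 tested windows had fewer raw counts in auxin (median log2 −0.51), and their scaled median was 0.13 above that of the other tested windows (−0.08 to 0.37). On the other chromosomes, 54 of 74 did (median −0.49), and the scaled median was 0.16 above the rest (0.06 to 0.34), at percentile 87.4 of matched random lists. Windows inside protein-coding genes, 502 of those tested, had a median raw log2 ratio of −0.62 and differed from the rest after scaling by 0.05 (−0.02 to 0.14), within counting error.

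The number of windows with a count was compared at an equal total of window counts, since the depth of the libraries was unknown. Of the 15703 windows, 2270 had a count in both columns, 974 in ETOH alone and 787 in auxin alone, while 11672 (74.3%) had none. With the ETOH column thinned to 351565 counts, 3060.2 windows had a count on average over 20 draws, against 3057 in auxin, whereas 1836.8 against 1719 had at least 3 counts. With 21ur-2844 left out and the ETOH column thinned to 306254 counts, 3154.5 and 3056 windows had a count. Without the 10 most abundant windows, and with the ETOH column thinned to 125555 counts, 3039.7 and 3047 did. The window of 21ur-1 (IV:16687107-16687127), which overlapped another window, had 0 counts in both columns. It shared all but 3 bases at its 5′ end, and 7.56% of such plus-strand windows had a count. Its 0 counts therefore do not show that the precursor was absent. A count was present in 3.62% (3.17 to 4.11) of the 6329 windows that overlapped another on the same strand and in 40.6% (39.6 to 41.6) of the 9374 that did not.

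**Figure D4:**
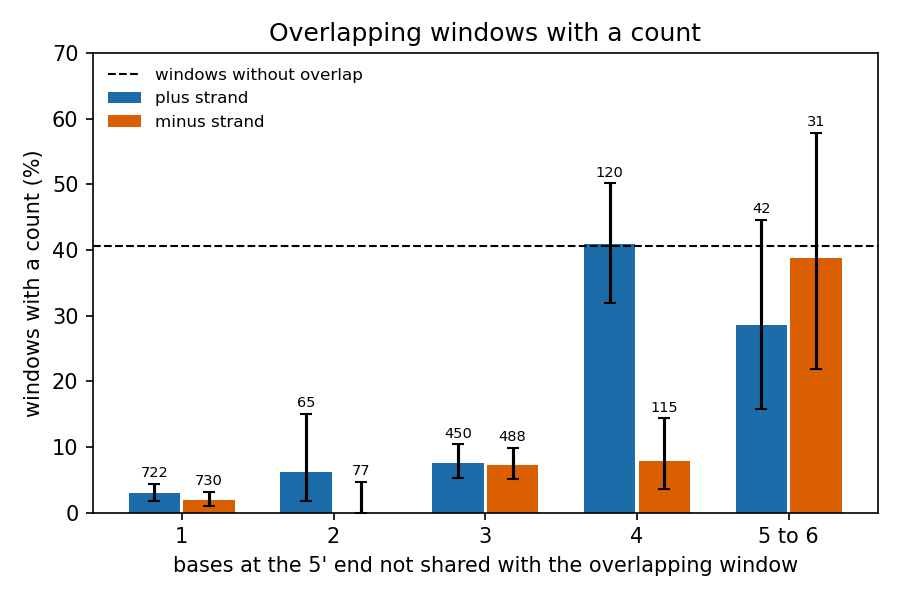
Percent of overlapping windows with a count in either column (vertical) by the number of bases at the 5′ end that the window did not share with its overlapping partner (horizontal), for both strands, with 95% Clopper-Pearson intervals and the number of windows above each bar. The share reached 40.8% at 4 bases on the plus strand and 38.7% at 5 to 6 bases on the minus strand, near the 40.6% of windows without overlap (dashed line), and was 28.6% at 5 to 6 bases on the plus strand.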

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

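Settings chosen only after the result was seen were the removal of 21ur-2844 (totals and detection), of unlocated windows and of windows over structural RNA. So were the removal of overlapping windows (for totals and for all groups of windows) and the minimum of 100 counts. For counts of windows and named windows, so was the prior count of 0.5. No paired analysis was possible because the 3 libraries of each condition were pooled into 1 column; fits with a replicate block, leave-one-out, DESeq2's Wald test, estimated correlations, the sign-flip test, scaling to other RNA and the motif alternatives were not run. The total ratio of 0.763 became 0.871 without 21ur-2844, 0.871 with located windows alone and 0.748 without the 10 most abundant. The detection ratio of 0.999 was 1.002 without the 10 most abundant windows and 0.969 without 21ur-2844, and became 0.936 at 3 or more counts. Against 196 lower and 111 higher windows, there were 439 and 36 without scaling (prior count 2), 533 and 508 without a filter (more windows of few counts entered) and 27 and 7 at 100 or more counts (fewer windows entered); 70 were higher with library totals and 73 with filterByExpr. The excess of abundant windows was 0.48 with filterByExpr and 0.27 for the top 25%; the cause was not tested. Without scaling, the log2 ratio changed sign for 21ur-12226 (−0.16), 21ur-6064 (−0.16), 21ur-2937 (−0.0645), 21ur-5622 (−0.24), 21ur-4429 (−0.14) and 21ur-12947 (−0.11), by the common shift alone. The small cluster stayed above the other windows by 0.40 to 0.45 and the large cluster below by −0.39 to −0.35 under the alternatives run.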

Other observations

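In this part, the test on neighbouring windows was chosen before its result was seen. The comparisons of the abundant windows and of the small cluster with the other windows were also planned, apart from the random lists and some of the alternatives, but their use to weigh an explanation, like the other tests, was chosen only afterwards. Chromosome V, singled out after its values were seen, held 20 tested windows with a median raw log2 ratio of −0.20 and a scaled median of 0.42, at percentile 99.0 of matched random lists. Windows inside genes on the opposite strand (280 tested) differed from the rest by 0.10 (−0.00 to 0.19), and those on the same strand (222 tested) by 0.01 (−0.11 to 0.09). Among windows on the mitochondrial genome, also singled out after their values were seen, 21ur-12226 had 17114 counts in ETOH and 15366 in auxin, whereas 21ur-14062 had 158 and 66 and 21ur-15578, which lay over a ribosomal RNA gene, had 269 and 116. Of other windows over structural RNA genes, 21ur-1009 had 268 and 90 counts, 21ur-3398 had 50 and 12, and 21ur-9348 had 123 and 134.

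Most windows had no count in either column. Windows farther from the annotated position did not have a count less often. Of windows without overlap on chromosome IV, 45.6% had a count at 30 or more bases from that position, against 32.2% under 20 bases. This cannot decide whether a displacement between reads and windows was the main reason. Displacement differed along the chromosome, so these sets also differed in region, and it was measured against the annotation, not against the reads. Overlap is a candidate explanation for part of the pattern, since 3.62% of overlapping windows had a count, against 40.6% of the others. The share rose to 40.8% for plus-strand windows with 4 bases of their own at the 5′ end (7.56% with 3, and 28.6% of 42 windows with 5 to 6, interval 15.7 to 44.6) and to 38.7% for minus-strand windows with 5 to 6 (7.83% with 4), as it would if most reads began at a fixed base of the window and were discarded when that base lay in 2 windows. A displacement between reads and windows and a low abundance of the windows without overlap stay open, and no biological explanation was tested.

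The total was lower in auxin. Reads of another RNA in 21ur-2844 as the whole cause are argued against by the ratio of 0.871 that remained without it. A common factor as the sole difference between the columns is argued against by the 0.42 (log2) between the abundant windows and the rest (0.27 with the most abundant 25%). That gap cannot say how much of the lower total came from depth, which was unknown. For 21ur-2844 itself, reads of the snoRNA T26A8.6 are a candidate source: the window would overlap the gene up to a displacement of 37 bases, and both flanking windows were displaced by 14, which is also the distance from the window's end to the 5′ end of the gene. A difference in depth as part or all of the cause of the lower total stays open. A difference between libraries (library kits included) and an effect of the loss of ISW-1 also stay open. The pooled columns held no replicates and no windows chosen for other RNA to scale by, although 10 piRNA windows lay over structural RNA genes.

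Windows of the large cluster were lower than those of the small cluster. A difference in abundance between the clusters as the cause is argued against, since the small cluster lay at percentile 100 of random lists matched on abundance and stayed 0.402 to 0.450 above the other windows under the alternatives run. Depth, being a single factor for all windows, cannot set the clusters apart. A difference between libraries unrelated to the treatment and a regional effect of the loss of ISW-1 may each account for it, and neither was tested.

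A hypothesis was that precursors close to each other share their change. Over 188 pairs of neighbouring tested windows within 500 bases on chromosome IV, Spearman's rho of the scaled log2 ratios was 0.0557 and Pearson's r 0.0618, across windows that are not independent replicates. The middle 95% of 1000 shuffles within region and abundance decile ran from −0.151 to 0.130, so rho lay within the range of shuffles and the hypothesis was neither borne out nor excluded.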
